A study of Mus musculus with 7 samples.

How the data were processed

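Gene expression was measured in prostate RNA from 7 samples of mice of the C57Bl/6 strain on 2-colour Agilent mouse arrays. Per the labels, 3 samples came from the PB-NICD model, in which a Cre recombinase driven by the ARR2PB prostate promoter switches on the Notch1 intracellular domain from the ROSA locus and the mice develop prostatic intraepithelial neoplasia. The 4 control samples came from ROSA(N1IC) mice that the labels describe as wild-type for this domain. Per the labels' protocols, total RNA was extracted with Trizol and labelled by direct cDNA synthesis. The prostate cDNA carried an Alexa Fluor dye read in the red channel, and a universal mouse reference RNA carried another read in the green channel on every array. The dyes were not swapped, so every ratio runs from sample to reference and an effect of the dye that depends on the probe is the same on all arrays.

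Per the file headers, the spot intensity of each channel was read with Agilent Feature Extraction 10.7.3.1. The deposited intensity columns used here are the median pixel signals of spot and local background, which are not normalized, and the processed signals, which the software had background-subtracted and dye-normalized within the array. The LogRatio column is, per the file headers, the log10 of red over green processed signal. It was used to check the direction of the ratio and to match the authors' value table to the arrays. On a log2 scale it also gave the values of the alternative with processed signals. The other deposited columns, flags of 0 or 1 per spot and channel, mark spots that are well above background, saturated or outliers in pixel uniformity or among replicate spots. The authors also deposited a value table on what its values show to be a log2 scale centred near 0, with column medians from -0.01 to 0.00. Its normalization method is not given in the sources used here. Each of its columns correlated across probes with the log2 ratio of its own array at r = 0.846 to 0.894. After each probe was centred over the arrays, r with the own array was 0.510 to 0.712 and with any other array at most 0.358, so the columns could be matched and the direction of the table was that of red over green.

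From the scanner values, background was corrected with normexp at an offset of 50 on the median spot and median background signals, followed by loess within each array, in limma 3.58.1 under R 4.3.3. Mean spot signals had been planned, but the scanner columns used here hold median signals. Control spots had a weight of 0 in loess and were then removed, and outlier spots in either channel were set to missing. Spots of the same probe were averaged. No scaling between arrays was applied. A probe was tested if its sample channel was well above background on at least 3 arrays. A further criterion, at least 2 values in each group, was added because outlier spots were missing. Where several probes of a gene passed, the brightest in the sample channel was used.

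The arrays held 45018 spots, of which 1639 were control spots, and 41174 probes. The scanner files give accessions and no gene names. Through the RefSeq table of the GRCm38.p6 assembly, matched on accessions without versions, 24375 probes received a gene symbol and 16799 did not. The files use an older genome build, so no coordinates are given. After filtering, 16939 items were tested, 11824 named genes and 5115 transcripts without a symbol here, and 10387 items had values on all 7 arrays. More than 1 probe was tested for 3311 genes. Of 143 called genes with several probes, 14 had a probe of opposite sign and 49 had another probe whose unadjusted p was not below 0.05.

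The sample channel was dim. Its median spot signal was 69 to 107 per array over a median background of 53 to 55, against 325.5 to 423 over 24 to 27 in the reference channel. Between 45.3% and 67.2% of probes were well above background in the sample channel, 6.02% to 17.8% of spots were marked as outliers, and no spot was saturated. The offset of 50 draws the ratios of dim spots towards each other, so changes of dim genes are understated, and a gene dim in both channels sits near a log2 ratio of 0. Where a gene was not well above background on any array of a group, brighter over dimmer is given as "at least N-fold", the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the dim probe's own signal, taken in the sample channel after loess and Aquantile and open to dye bias. The number of arrays, 4 and 3, limits the precision.

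PB-NICD was compared with control by lmFit and eBayes in limma with group as the only term, two-sided, with Benjamini-Hochberg adjustment over the 16939 items and a threshold of 0.05. Fold changes are differences of mean log2 ratio, PB-NICD minus control. The 26 gene lists fixed before the data were examined covered Notch target genes, Notch receptors, ligands and core machinery, NF-kB targets, cell cycle, androgen-responsive and prostate secretory genes, luminal, basal, luminal progenitor, urothelial, neuroendocrine, smooth muscle, fibroblast, macrophage, lymphocyte, neutrophil, endothelial, adipocyte, skeletal muscle, seminal vesicle and erythroid genes, immediate-early and interferon-stimulated genes, endoplasmic reticulum stress and protein folding, apoptosis and anoikis, epithelial-mesenchymal transition and oxidative phosphorylation. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 25 lists, and again with an estimated correlation and with fry, which used members with values on all 7 arrays and covered the 22 lists with at least 5 of them. The lists overlap in places, Sox9, Cd44, Acta2 and Myc among the shared members.

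The genes named were chosen by a rule fixed before the data were examined. It took the 12 largest rises and 12 largest falls among genes with a symbol, an adjusted p below 0.05 and all 3 PB-NICD arrays on the same side of all 4 controls. It also took Notch1 and, from each list, up to 4 members with the smallest unadjusted p. As outlier spots were missing, the side was judged on the measured arrays alone, a change from the fixed rule. With its left-out spot kept, Klk1b21 would not have met the fixed rule. Further list members are named as examples of their list, and any other gene is said to have been chosen after its values were seen. In 26 of the 118 genes named by the rule another probe was tested.

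The procedure was tested on simulated data. Values were drawn with each item's mean, spread and missing values, and 200 of 16939 items were changed. The fit recovered 56% of 2-fold and 97% of 4-fold changes, and 5 of 158 calls were false. The draws were normal, independent between items and equal in spread in both groups, without a slide effect or an array that stands apart. They check the fit and do not give the error rate on the real arrays, where slide and PB-NICD 1 matter. The arrays lie on 2 slides, which were also 2 scans, so slide and scan are the same split. Slide 1 held control 1, control 2 and PB-NICD 1, and slide 2 held the other 4 arrays. Alternatives tried were no background subtraction, the software's processed signals, median centring in place of loess, Aquantile between arrays, the sample channel alone, an offset of 10, no filter on dim probes, a filter asking for signal on all 7 arrays, outlier spots kept, the mean of a gene's probes, the authors' value table, slide as a fixed or random block and each slide alone, the replicate number as a block, array weights, trended robust eBayes, each array left out in turn and a 2-fold threshold. Identical sample signals made up at most 3.41% of spots in any pair of arrays, so no array was a copy of another. The labels do not say that samples came from separate animals, so p-values measure only the spread between these samples, which may be technical.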

Results

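Expression was measured in 7 prostate samples, each set against the same universal mouse reference RNA on its own 2-colour array. Per the labels, the 4 control samples came from mice carrying the silent ROSA(N1IC) allele, and the 3 PB-NICD samples from mice that also carry the ARR2PB-Cre transgene. This transgene is meant to switch on the Notch1 intracellular domain, the active form of the Notch1 receptor, in the prostate. Whether the sample labelled PB-NICD 1 expressed the domain is open, as given below. Values are log2 ratios of sample over reference, and a fold change is the PB-NICD mean minus the control mean. The share of probes well above background in the sample channel was 52.8% ± 8.51 (SD, n = 4) on the control arrays and 60.8% ± 6.75 (SD, n = 3) on the PB-NICD arrays. In the reference channel it was 81.3% ± 6.54 and 69.7% ± 8.58, and each PB-NICD array lay below both controls of its slide. The median sample signal was 78.1 ± 9.99 and 100.5 ± 10.8, and each PB-NICD array lay above both controls of its slide. What this does to the ratios of dim genes was not tested. Across items measured on all arrays, the control arrays correlated with each other at r = 0.927 to 0.962. PB-NICD 2 and PB-NICD 3 correlated at r = 0.954, PB-NICD 1 with either of them at 0.834, and arrays of different groups at 0.778 to 0.904. These correlations run across genes, which are not independent replicates. PB-NICD 1 lay on slide 1 with control 1 and control 2, and the other 4 arrays lay on slide 2. With each slide filtered and fitted anew, the median change of all items was -0.24 within slide 1 and -0.03 within slide 2. List medians within a slide are to be read against that of all items there.

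The comparison of PB-NICD with control asks which genes differ in prostates labelled as those of the PB-NICD model. Notch1 itself and the Notch target genes Heyl and Hes1 rose. Genes of protein folding in the endoplasmic reticulum fell as a group, led by the chaperone Hspa5 and the degradation factor Derl3, and the basal cell keratins Krt5 and Krt15 fell. The largest rises were those of Pnliprp2, a lipase of the pancreatic lipase family, by 5.42 ± 0.42 (log2, SE) and of Upk3a, a protein of the urothelial plaque, by 4.83 ± 0.35. The largest falls were those of C1ra, a protease of the classical complement pathway (-5.67 ± 0.39), and Fgl1, a fibrinogen-like secreted protein (-5.05 ± 0.42).

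Notch1 rose by 2.20 ± 0.22 (adjusted p = 0.00145), from a control mean of 0.44 ± 0.33 (SD, n = 4) to 2.65 ± 0.09 (SD, n = 2). Its log2 ratios were 0.05, 0.30, 0.77 and 0.66 on control 1 to control 4, 2.58 on PB-NICD 2 and 2.71 on PB-NICD 3. On the array labelled PB-NICD 1 the spot was marked as an outlier and left out. With outlier spots kept it read 0.64, within the range of the controls, and the change was then 1.56 with adjusted p = 0.110. The array is therefore called the array labelled PB-NICD 1, and each PB-NICD mean that includes it draws part of its direction from it. Whether the only Notch1 probe lies in the part of the gene that the transgene carries is not given in the sources used here, so the probe checks the labels only in so far as it does. With slide as a fixed block Notch1 rose by 1.93 (adjusted p = 0.000109), and within slide 2 by 1.93 (adjusted p = 0.000532). Slide 1 gave no value because its only PB-NICD spot was left out. Median centring in place of loess gave 1.49 with adjusted p = 0.293.

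Among the 21 Notch target genes measured, Heyl and Hes1, transcriptional repressors induced by Notch signalling, rose and none fell. Adjusted over the list alone, 5 rose and 1 fell. Heyl rose by 2.44 ± 0.24 (adjusted p = 0.0012) and Hes1 by 1.19 ± 0.16 (adjusted p = 0.00412), each higher on all 3 PB-NICD arrays than on any control by the probe used. On the array labelled PB-NICD 1, Heyl stood at 1.56 against a control mean of -0.17, and Hes1 at 2.44 against 1.53. The other Heyl probe gave 1.42 ± 0.41 (unadjusted p = 0.00698) and, with outlier spots kept, read 0.24 on the array labelled PB-NICD 1, within the controls' range of -0.32 to 0.25. With slide as a fixed block the changes were 2.36 for Heyl and 1.16 for Hes1. Igf1r, the receptor of insulin-like growth factor 1 (0.51, adjusted p = 0.0797), and Notch3 (1.12, adjusted p = 0.103) did not pass over all genes. With slide as a fixed block both passed, Igf1r at 0.47 (adjusted p = 0.0324) and Notch3 at 1.02 (adjusted p = 0.0246), and as a random block Igf1r alone (adjusted p = 0.0402, against 0.0517 for Notch3). The other Igf1r probes gave 0.14 and 0.28. Nrarp, a feedback inhibitor of Notch signalling, read 0.31 on the array labelled PB-NICD 1 and 3.33 and 3.42 on PB-NICD 2 and PB-NICD 3, against a control mean of 0.17 ± 0.41 (SD, n = 4). Its change of 2.19 had an adjusted p of 0.131, and that of Hey1, another repressor of the same family, was 1.00 with adjusted p = 0.441. As a list the targets were not called (adjusted p = 0.243, 0.714 with an estimated correlation). Their median was -0.09, their mean 0.23 and the direction of the test upward. The median was -0.09 with slide as a fixed block, -0.05 within slide 1 and -0.14 within slide 2, and turned positive with the software's processed signals, with median centring and with the sample channel alone.

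**Figure D1:**
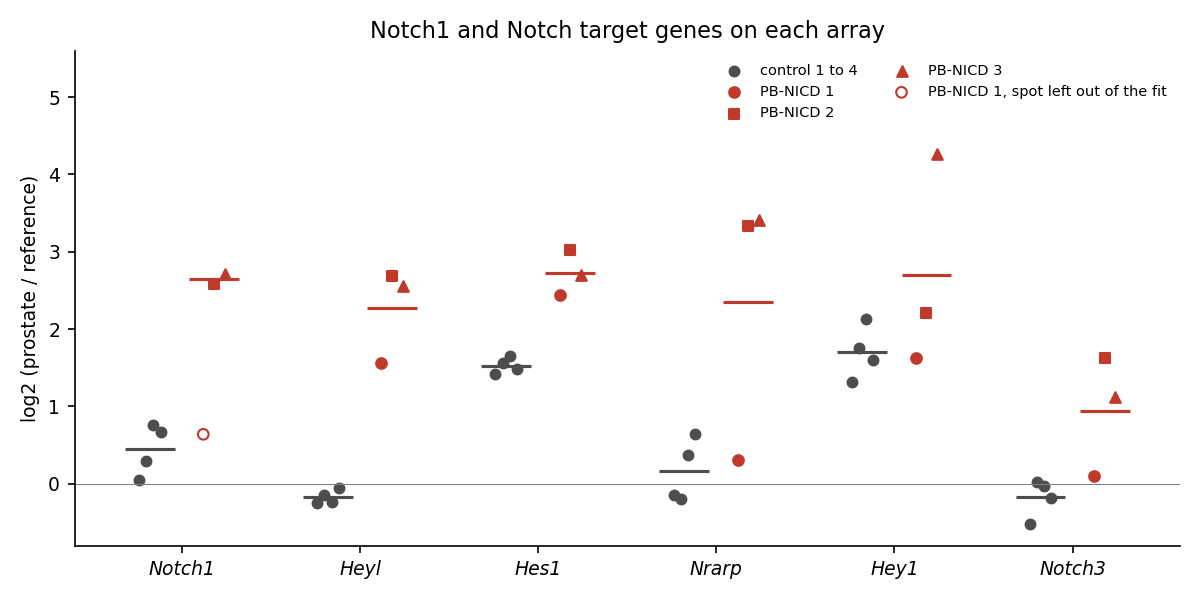
Log2 ratio of sample over reference (vertical axis) for Notch1, Heyl, Hes1, Nrarp, Hey1 and Notch3 on each of 4 control and 3 PB-NICD arrays, with bars at the group means and an open circle for the Notch1 spot of the array labelled PB-NICD 1 that was left out of the fit. By the probes used Heyl and Hes1 lie above every control on all 3 PB-NICD arrays, while Nrarp does so on PB-NICD 2 and PB-NICD 3, at 3.33 and 3.42.

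Among the genes that rose most, Mgst1, a microsomal glutathione transferase, rose by 3.26 ± 0.22 (adjusted p = 0.000127), Nxpe4 by 4.08 ± 0.58 and Wfdc3, a protein with whey acidic protein domains, 8.57-fold. Kcnf1, a potassium channel subunit, was not well above background on any control array and was at least 7.85-fold higher in PB-NICD (adjusted p = 0.0142). Cbs, an enzyme of cysteine synthesis from homocysteine, rose by 2.31 ± 0.23, the tetraspanin Tspan7 by 2.16 ± 0.24 and the membrane glycoprotein Emb by 2.38 ± 0.35. Klk1b21, a tissue kallikrein, rose by 2.40 ± 0.22 from PB-NICD 2 and PB-NICD 3, since its spot on the array labelled PB-NICD 1 was left out. That spot read 0.50 if kept, at the control level, and the call was then lost. Members of the Klk1b family are close in sequence, so the probe may read relatives. Upk3a rests on 2 arrays in each group.

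Among the genes that fell most, C1s2, a complement protease of the same complex as C1ra, fell by 4.37 ± 0.27 (adjusted p = 7.76e-05). C1ra has a near-identical copy, C1rb, and the array may not separate them. Ren2, a renin gene, was not well above background on any PB-NICD array. It was at least 14.6-fold higher in control in the sample channel, the fold of its own signals there. Its log2 ratio changed by -4.69, and Ren1 fell by 3.04 ± 0.21. The other Ren1 probe gave -7.00, and where it took the place of the brightest, without control 2, control 4, PB-NICD 2 or PB-NICD 3, the change reached -7.14. The probes of both genes may read the same transcript, because the C57Bl/6 strain carries Ren1 alone. Cd4, the coreceptor of helper T cells, fell by 3.72 ± 0.30. Falls were also those of Fam163b (-4.88 ± 0.55), the ubiquitin ligase regulator Neurl4 (-4.41 ± 0.33), Ms4a5 (-4.13 ± 0.28) and the pore-forming gasdermin Gsdma (-3.52 ± 0.49). Fkbp11, a prolyl isomerase of the secretory pathway (-3.45 ± 0.20), and Agr2, a disulfide isomerase of secretory epithelia (-3.41 ± 0.29), fell as well. Fgl1, Gsdma and Agr2 had spots left out on control arrays. Col18a1, a basement membrane collagen, fell by 3.19 ± 0.25 on its brightest probe, whereas its other probe gave -0.35, and with the brightest probe missing its change was -0.32 within slide 2 (adjusted p = 0.382) and -0.33 within slide 1 (adjusted p = 0.216). It was -0.37 without control 2, -0.33 without control 4, -0.39 without PB-NICD 1 and -0.24 without PB-NICD 2, with no call.

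**Figure D2:**
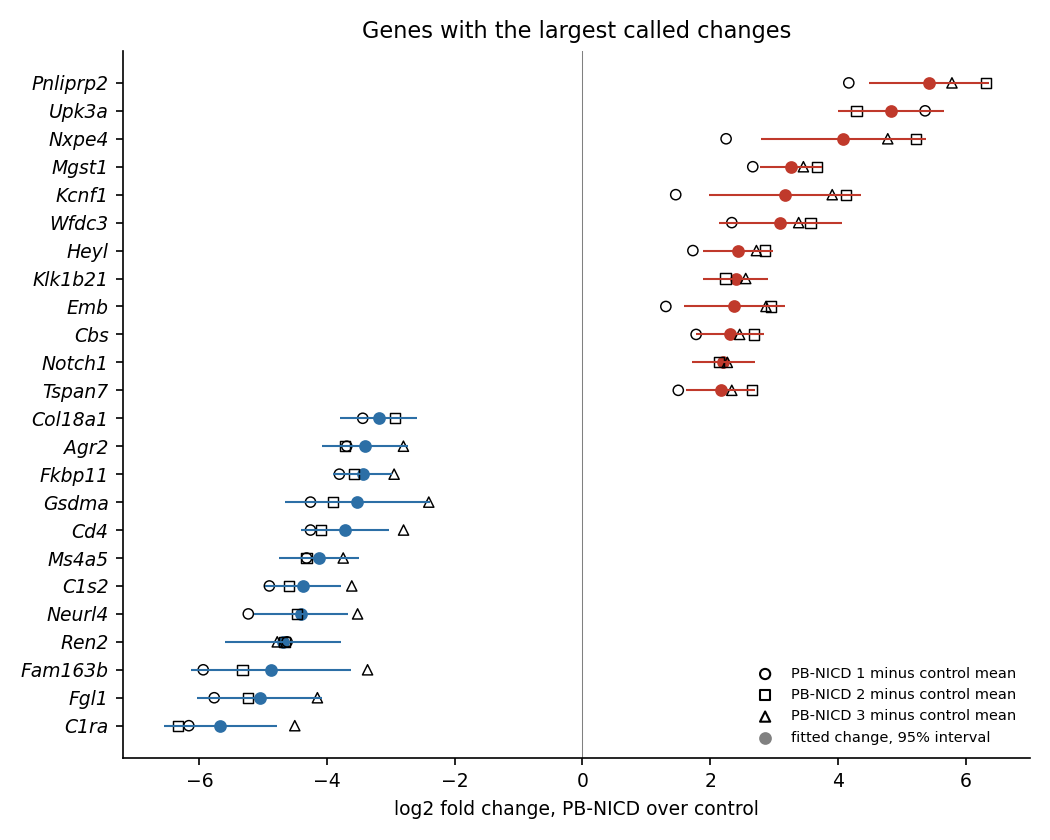
Fitted log2 change, PB-NICD minus control, of the 12 named genes that rose most and the 12 that fell most (horizontal axis), with 95% confidence intervals and open symbols for each PB-NICD array minus the control mean. The changes run from -5.67 for C1ra to 5.42 for Pnliprp2, and Notch1, Klk1b21, Upk3a and Col18a1 rest on 2 PB-NICD arrays.

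Endoplasmic reticulum stress and protein folding genes fell, 17 of the 24 measured and none rose, and 19 fell when adjusted over the list alone. Derl3, which takes part in the degradation of misfolded proteins, fell by 2.76 ± 0.17 (adjusted p = 7.76e-05), and the chaperone Hspa5 fell by 2.79 ± 0.26 (adjusted p = 0.00132, from 2 PB-NICD arrays). Asns, the asparagine synthetase, fell by 1.61 ± 0.13 and Edem1, a mannosidase-like protein of the degradation pathway, fell by 1.71 ± 0.17. The other probes of Edem1 gave -0.97 and -0.93. Among the remaining falls were the chaperone partners Sdf2l1 (-2.48), Dnajc3 (-2.21) and Dnajb9 (-2.15), the chaperones Hyou1 (-1.52), Hsp90b1 (-1.51) and Calr (-1.46), and the stress transcription factors Atf4 (-1.01) and Atf6 (-0.83). Herpud1, Canx, Ddit3, Xbp1, Trib3, Ero1b and Ern1 did not pass, with changes from -1.72 for Herpud1 (adjusted p = 0.0901) to 0.15 for Ern1. Hspa5 fell by 2.79 with slide as a fixed block and by 2.94 within slide 1. The array labelled PB-NICD 1 lay below all controls for 19 of 23 members, PB-NICD 2 for 20 of 21 and PB-NICD 3 for 20 of 23. The list's median was -1.39 (adjusted p = 2.44e-22), and it was the 1 list whose call held with an estimated correlation (adjusted p = 0.0472). Its median was -1.42 with slide as a fixed block, -1.65 within slide 1 and -1.27 within slide 2.

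**Figure D3:**
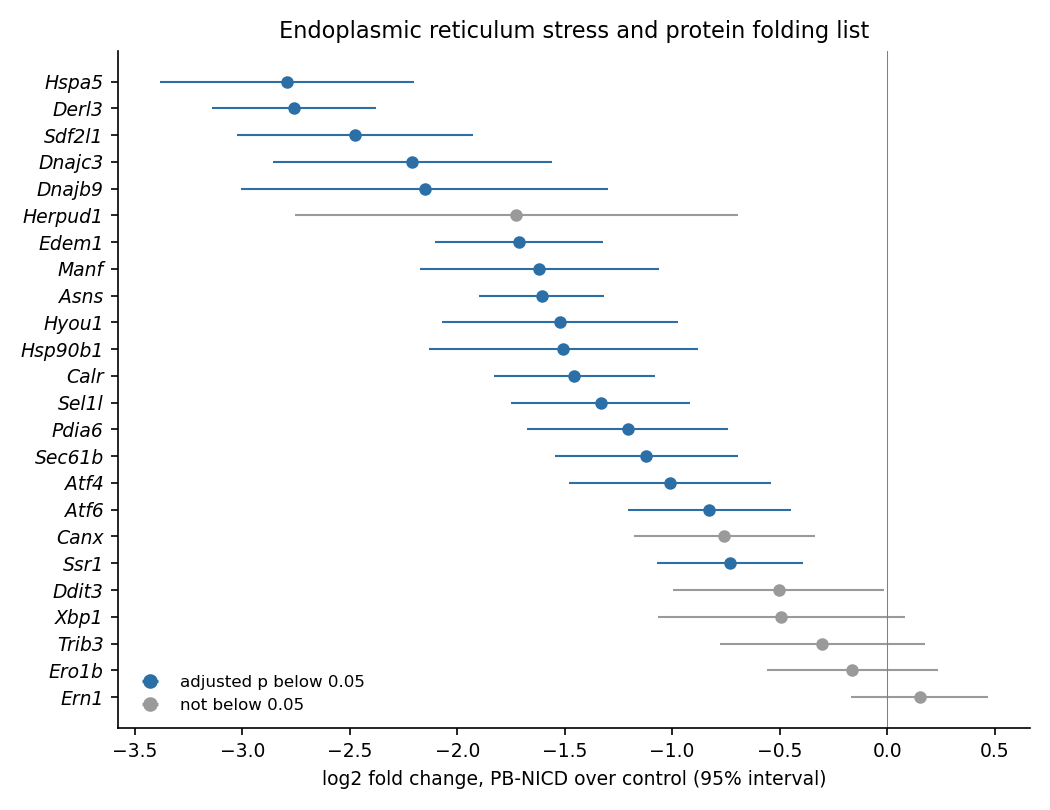
Fitted log2 change, PB-NICD minus control, of the 24 measured genes of endoplasmic reticulum stress and protein folding (horizontal axis), with 95% confidence intervals and in blue the genes with an adjusted p below 0.05. The changes run from -2.79 for Hspa5 to 0.15 for Ern1, and 17 of the 24 genes fell.

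Oxidative phosphorylation genes fell, 3 of 36 over all genes and 21 adjusted over the list alone, and none rose. Ndufb9 of complex I fell by 1.32 ± 0.18, Uqcrq of complex III fell by 1.08 ± 0.17 and Sdhc of complex II fell by 0.76 ± 0.17 (adjusted p = 0.0473), whereas Ndufa1 stood at -0.86 without passing (adjusted p = 0.0569). The list median was -0.50 (adjusted p = 1.52e-11; adjusted p = 0.512 with an estimated correlation). It was -0.50 with slide as a fixed block, -0.75 within slide 1 and -0.31 within slide 2, and per array -0.70 on the array labelled PB-NICD 1, -0.39 on PB-NICD 2 and -0.27 on PB-NICD 3. Smooth muscle markers had a median of -0.55 (adjusted p = 8.35e-07; adjusted p = 0.512 with an estimated correlation), -0.54 with slide as a fixed block, -0.63 within slide 1 and -0.40 within slide 2. Over all genes 1 of their 23 members fell, Tpm2, a tropomyosin (-0.89 ± 0.16), and 12 fell when adjusted over the list alone, the contractile genes Cnn1 (-0.84), Hspb6 (-0.52) and Csrp1 (-0.66) among them.

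Basal epithelial markers had a median of -0.16 (adjusted p = 0.0412; adjusted p = 0.507 with an estimated correlation). Over all genes 4 of 19 fell and none rose, and adjusted over the list alone 6 fell and Egfr, the epidermal growth factor receptor, rose. Krt5 fell by 1.84 ± 0.17 (adjusted p = 0.000738). Krt15 (-1.41 ± 0.23), Lgals7, a galectin of stratified epithelia (-1.38 ± 0.24), and Itga6, an integrin of basal cells (-0.63 ± 0.12), also fell, while Krt14 stood at -0.55 (adjusted p = 0.144). The call of the list was lost with slide as a fixed block (-0.19, adjusted p = 0.0741) but not as a random block (-0.17, adjusted p = 0.0475), and was lost without control 2 (-0.14, adjusted p = 0.0525) and without PB-NICD 3 (-0.33, adjusted p = 0.125). Within slide 1 the median was -0.35 and within slide 2 -0.25, and with each slide filtered and fitted anew -0.28 and -0.36.

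Androgen-responsive and prostate secretory genes had a median of -0.35 (adjusted p = 0.0412; adjusted p = 0.714 with an estimated correlation). Of 36 members 5 fell and Mgst1 rose, and adjusted over the list alone 10 fell and 2 rose. The falls were those of C1s2, Ren1, the calcium channel Trpv6 (-1.17), the Golgi mannosidase Man1a (-2.36) and 9530003J23Rik (-3.11). The last was not well above background on any PB-NICD array and was at least 9.59-fold higher in control in the sample channel alone. This is the fold of its own signals in that channel and does not bound the change of its ratio to the reference. The secretory protein genes Sbp, Sbpl and Pbsn did not pass over all genes. Sbp read 0.54 on the array labelled PB-NICD 1, 4.73 on PB-NICD 2 and 9.40 on PB-NICD 3 against a control mean of 10.30 (adjusted p = 0.126), and the change of Pbsn was -1.19 (adjusted p = 0.187). The list median was -0.81 on the array labelled PB-NICD 1, -0.25 on PB-NICD 2 and -0.10 on PB-NICD 3. It was -0.32 with slide as a fixed block (adjusted p = 0.00441), -0.81 within slide 1 and -0.16 within slide 2, and with each slide filtered and fitted anew, which changes the members and probes that enter, -0.60 and -0.097. Without PB-NICD 1 the call was lost (-0.23, adjusted p = 0.287), as without control 1 (-0.27, adjusted p = 0.0664) and without control 4 (-0.32, adjusted p = 0.0787).

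Fibroblast and extracellular matrix genes had a median of -0.24 (adjusted p = 0.0412; adjusted p = 0.714 with an estimated correlation), with no call among 30 members over all genes or adjusted over the list alone. Their lowest p was that of Fbln1, a fibulin (-0.57, adjusted p = 0.137). The call of the list was lost with slide as a fixed block (-0.19, adjusted p = 0.0901) but not as a random block (-0.22, adjusted p = 0.0475). It was lost without control 1 (-0.17, adjusted p = 0.0764), control 4 (-0.23, adjusted p = 0.0787), PB-NICD 2 (-0.13, adjusted p = 0.414) or PB-NICD 3 (-0.25, adjusted p = 0.12). The median turned positive with median centring, where it was -0.089 relative to the median of all items (0.14). It was -0.18 within slide 1 and -0.23 within slide 2, and with each slide filtered and fitted anew -0.25 and -0.23. Cell cycle genes had a median of 0.10 (adjusted p = 0.0412; adjusted p = 0.714 with an estimated correlation), and none of 34 members was called in either way. The median was 0.43 on the array labelled PB-NICD 1, -0.13 on PB-NICD 2 and -0.04 on PB-NICD 3. It was 0.17 with slide as a fixed block, 0.29 within slide 1 and 0.07 within slide 2, and turned negative with no background subtraction and without PB-NICD 1 (-0.07, adjusted p = 0.352). The call was also lost without control 3 (0.05, adjusted p = 0.0917) and control 4 (0.06, adjusted p = 0.204).

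The other 17 tested lists were not called, neither over these values nor with slide as a fixed or random block. In what follows each list's median is given with, in parentheses, the median with slide as a fixed block, within slide 1 and within slide 2. Those within slide 1 are to be read against the median of all items there, -0.24 with the slide filtered and fitted anew. Notch receptors, ligands and core machinery had a median of 0.02 (0.06, 0.03, 0.08), and of 20 members Notch1 rose over all genes, while adjusted over the list alone the ligand Jag2 also fell (-0.56), as it did over all genes with slide as a fixed block (-0.59, adjusted p = 0.0286). NF-kB targets had a median of 0.06 (0.10, 0.11, 0.00). Of 21 members Gadd45b, a stress-response gene, rose by 1.03 ± 0.18, and adjusted over the list alone Sod2 and Cd44 also fell. Luminal epithelial markers had a median of -0.04 (-0.17, -0.51, 0.17), with -0.67 on the array labelled PB-NICD 1, 0.21 on PB-NICD 2 and 0.33 on PB-NICD 3, and the sign of the median turned under 4 of the other scalings. Of 25 members 3 fell, also adjusted over the list alone, the surface glycoprotein Cd24a (-2.06), the prolactin receptor Prlr (-1.23) and the epithelial transcription factor Ehf (-1.10). Cd24a had spots left out in both groups. With outlier spots kept, the Ehf probe used read 1.38, 1.61 and 1.88 on the 3 PB-NICD arrays and 2.68 to 2.86 on the controls. The other Ehf probes gave -1.45 and -1.71. Where another probe took the place of the one used, the change was -0.49 without PB-NICD 1 (adjusted p = 0.247) and -1.71 without PB-NICD 3 (adjusted p = 0.284). Within slide 1 it was -3.03, also by another probe. Luminal progenitor and proximal duct markers had a median of -0.09 (-0.12, -0.18, -0.03). Of 25 members Gsto1, a glutathione transferase, fell by 0.95 ± 0.18, and adjusted over the list alone 5 fell and 3 rose. Urothelial markers had a median of -0.25 (-0.26, -0.17, -0.40) but a mean of 0.47 and a test pointing upward. Of 6 members Upk3a rose, and Foxq1 (-0.56) fell when adjusted over the list alone. Neuroendocrine markers had a median of -0.29 (-0.26, -0.10, -0.27). Of 8 members the adhesion molecule Ncam1 fell by 1.28 ± 0.18 in both ways of adjusting, on its brightest probe, while its 3 other probes gave 0.39, 0.12 and 0.50. Interferon-stimulated genes had a median of 0.01 (0.03, 0.03, -0.03), and of 22 members the immunoproteasome subunit Psmb8 rose by 0.89 ± 0.16 in both ways of adjusting. Apoptosis and anoikis regulators had a median of -0.08 (-0.09, -0.21, -0.02). Of 26 members Bnip3l, a mitophagy receptor, fell by 2.20 ± 0.30 over all genes, and Dapk3 (-0.52) also fell when adjusted over the list alone. The other Bnip3l probe gave -0.04, and where it took the place of the brightest probe the change was 0.02 within slide 2 (adjusted p = 0.961) and without control 4 (adjusted p = 0.979), -0.045 without control 2, -0.11 without PB-NICD 2 and -0.028 without PB-NICD 3.

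T, NK and B lymphocyte markers had a median of 0.02 (0.08, 0.16, -0.03), a mean of -0.15 and a test pointing upward, and of 21 members Cd4 fell in both ways of adjusting. Endothelial markers had a median of -0.05 (-0.03, -0.10, 0.00), with no call among 17 over all genes and a fall of the sialomucin Emcn (-0.89) adjusted over the list alone. Immediate-early genes had a median of -0.10 (-0.10, 0.03, -0.17), with none of 23 called over all genes, while Ier2 (0.67) rose and Ccn1 (-0.66) fell when adjusted over the list alone. In the following lists no member was called in either way. Macrophage and dendritic cell markers had a median of 0.00 over 22 members (0.03, -0.02, 0.07), a mean of -0.01 and a test pointing upward. Neutrophil markers had a median of -0.07 over 7 members (-0.02, 0.02, -0.03), a mean of 0.06 and a test pointing upward. Adipocyte markers had a median of -0.24 over 10 members (-0.24, -0.26, -0.18), erythroid genes of -0.17 over 5 members (-0.20, -0.30, 0.04), skeletal muscle markers of -0.35 over 20 members (-0.29, -0.75, -0.07) and epithelial-mesenchymal transition genes of -0.25 over 21 members (-0.24, -0.04, -0.25). The adjusted p of the lists not called ran from 0.0575 for skeletal muscle to 0.909 for endothelial markers. Seminal vesicle genes had 3 tested members, too few for a test, with a median of -1.25 (0.07, -2.43, 0.84) and no call. Their secretory genes Svs4 and Svs5 read 9.36 and 8.33 on control 2, and Svs4 read 3.42 on the array labelled PB-NICD 1.

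**Figure D4:**
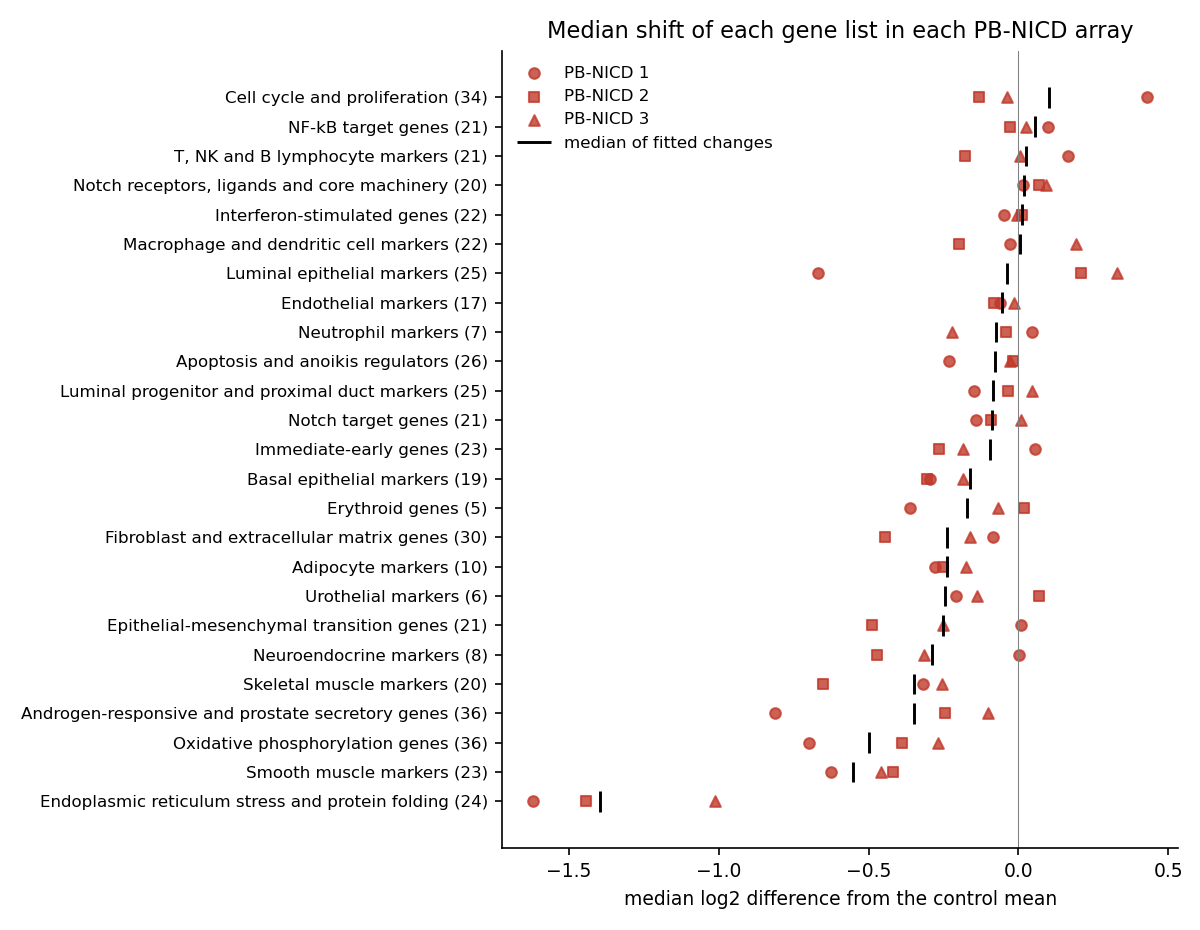
Median log2 shift from the control mean of each of the 25 tested gene lists on each PB-NICD array (horizontal axis), with the number of genes tested in parentheses and a black bar at the median of the fitted changes. The endoplasmic reticulum list lies at -1.62, -1.44 and -1.01 on the 3 arrays, whereas the luminal list lies at -0.67 on the array labelled PB-NICD 1 and at 0.21 and 0.33 on the others.

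In total 461 of 16939 items changed by limma with Benjamini-Hochberg adjustment, of which 70 rose and 391 fell, and 272 changed at least 2-fold. Of these 389 were named genes, 58 that rose and 331 that fell. At an unadjusted p below 0.05 there were 2455 items, and 3150 items (18.6%) had all measured PB-NICD arrays on the same side of all measured controls. Chance gives 5.71% for an item with values on all 7 arrays, as 10387 of the 16939 had. For items with missing values it gives more, so 5.71% understates the chance share of the whole. The camera test called 7 of the 25 lists, 1 with an estimated correlation, and fry, which tests whether a list's genes move one way and does not compare them with other genes, called 3 (endoplasmic reticulum, basal and smooth muscle). Fry used members with values on all arrays and so covered 22 lists, with 14 of 24 endoplasmic reticulum genes, 12 of 19 basal genes and 9 of 23 smooth muscle genes, and on the same members camera called 6 lists. As many lists were called in 9 of the 35 ways to split the arrays into 4 and 3, so chance cannot be excluded for the count of lists. By single list, a camera p as small came in 1 of these ways, the real one, for the endoplasmic reticulum list. It came in 2 for basal and smooth muscle each, 3 for oxidative phosphorylation, 5 for androgen, 11 for fibroblast and 25 for cell cycle. The Notch target and Notch receptor lists, not called, also had 1. These ways do not keep the slides. With slide as a fixed block 1232 items changed (183 rose, 1049 fell), as a random block 836, within slide 2 683 (319 rose, 364 fell) and within slide 1, where the single PB-NICD array is assumed to vary like the controls, 3017 (152 rose, 2865 fell). All 46 named genes called beside Notch1 kept their call with slide as a fixed or random block, and 27 of 32 with a value did so within slide 2. With slide as a fixed block 20 further named genes passed (adjusted p = 0.00889 to 0.0475), 12 of them also with a random block. They were Igf1r, Jag2, Sod2, Tspan1, Crip1, Csrp1, Cnn1, Hspb6, Emcn, Ccn1, Dapk3 and Ndufa1 in both, and Notch3, Cd44, Lcn2, Mcm7, Upk1b, Pnpla2, Ier2 and Ifi27 with the fixed block. Leaving out control 1, 2, 3 or 4 gave 242, 232, 284 or 201 items, and leaving out PB-NICD 1 or PB-NICD 2 gave 1013 (489 rose, 524 fell) or 222. The share of rises, 15.2% here, was 42.6% with no background subtraction (615 of 1443 items), 43.8% with processed signals (496 of 1132), 51.2% with the sample channel alone (571 of 1116) and 39.3% with the authors' value table (1257 of 3196), so the predominance of falls depends on the scaling. It also depends on the arrays. With the scaling unchanged the share was 48.3% without PB-NICD 1, 46.7% within slide 2 and 39.9% with array weights. Without PB-NICD 2 it was 14.9% and without PB-NICD 3 8.82%. Median centring in place of loess left 1 call, a fall, and moved the median of all items from -0.04 to 0.14, a shift of 0.19. All 47 named calls, Notch1 included, kept their direction, with a fold that was in the median 0.76 of that after loess and a standard error 1.76 times as large. C1ra stood at -4.83 ± 0.51 (adjusted p = 0.0558), Pnliprp2 at 4.15 ± 0.63 (adjusted p = 0.237) and Cd4 at -3.25 ± 0.60 (adjusted p = 0.492), and the endoplasmic reticulum list kept its call with a median of -0.90.

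Of the 46 named calls beside Notch1, 24 held in all 7 fits that left out 1 array. A further 6, Upk3a, Klk1b21, Fgl1, Gsdma, Agr2 and Hspa5, held in the fits that gave them a value and had none in the others. Lost in at least 1 such fit were Col18a1, whose adjusted p reached 0.669, Bnip3l (0.979), Ehf (0.284), Sdhc (0.155), Prlr (0.136), Gsto1 (0.127), Tpm2 (0.0909), Itga6 (0.0857), Psmb8 (0.0807), Krt15 (0.0670), Cd24a (0.0650), Lgals7 (0.0613), Gadd45b (0.0591), Uqcrq (0.0512), Ndufb9 (0.0503) and Kcnf1 (0.050). Without control 1, 2, 3 or 4 the named calls kept were 36 of 45, 30 of 41, 39 of 46 and 30 of 42, and without PB-NICD 1, 2 or 3 they were 40 of 42, 30 of 40 and 39 of 43.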

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

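No test in this part was chosen after its result was seen. In each of 108 values, those of the named genes with 4 control arrays and the median log2 ratio of each gene list, the control array farthest from the rest was compared with the spread of the 4 controls. In 6 values 1 control stood apart, where chance alone would give 5.4. For Ncam1, an adhesion molecule of neural and neuroendocrine cells, control 4 read 1.75 and the others 1.30 to 1.36, a gap of 0.873 of the whole range. For Cd8a, the coreceptor of cytotoxic T cells, control 1 read -0.07 and the others -0.05, a gap of 0.906 of a narrow range. The median of the luminal progenitor and proximal duct markers was 0.42 on control 3 and 0.19 to 0.23 on the others, a gap of 0.852. The median of the urothelial markers was 1.71 on control 3 and -0.10 to 0.00 on the others, a gap of 0.946. On control 3 the spots of Upk3a and Upk2 were left out, so its median was taken over 4 of the 6 markers. The median of the neuroendocrine markers was 0.13 on control 1 and -0.35 to -0.30 on the others, a gap of 0.898. The median of the immediate-early genes was -0.53 on control 4 and -0.34 to -0.32 on the others, a gap of 0.903. No explanation of these values was tested.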

How the results depend on the processing

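No alternative was chosen after its result was seen. The endoplasmic reticulum list kept its direction and its call in every alternative run (median -1.65 to -0.90). Of 2761 values of named genes under the alternatives, 2433 kept their side of the threshold, 145 lost their call, 180 gained one and 3 reversed. Direction was compared only where the gene was called here or under the alternative, so turns of sign among uncalled values are not counted. Apart from median centring, 28 of 46 called genes kept their call wherever they had a value. Of these, 13 had a value in all 25 alternatives and 15 had none in some. Values within a slide come here from filtering and fitting that slide anew, with other members and probes than in the comparison of all arrays. The causes of the changes below were not tested unless stated.

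The count of changed items, 461, was 1443 with no background subtraction, 1132 with processed signals, 1 with median centring, 1116 with the sample channel alone, 3196 with the authors' value table, 1232 and 836 with slide as a fixed or random block, 3017 within slide 1, 1170 with array weights, 272 at 2-fold or more, and 201 to 1013 with 1 array left out. Without control 1, 2, 3 or 4 it was 242, 232, 284 or 201, and without PB-NICD 1 or 2 it was 1013 or 222. With the replicate number as a block 269 items were called, 234 of them among the 461, on 6 arrays, since control 4 has no partner and the same arrays without the block gave 201. The numbers do not pair the arrays, as same-numbered arrays correlated at 0.355, -0.399 and 0.223 in their deviations, while pairs on the same slide correlated at 0.22 to 0.46. Lists called, 7 here, were 3 with no background subtraction, 4 with signal on all 7 arrays, 3 with the authors' value table, 1 with an estimated correlation and 3 with fry.

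Notch1 was 1.49 with median centring and 1.56 with outlier spots kept, which brings back the spot on the array labelled PB-NICD 1, and 2.07 to 2.31 with 1 array left out. It had no value within slide 1, with signal asked on all 7 arrays or without PB-NICD 2 or 3, where too few spots are left. Bnip3l reversed to 0.023 within slide 2, with the replicate block and without control 4 (-2.20 to 0.023 with 1 array left out), because its other probe takes the place of the one then missing.

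The cell cycle list lost its call with no background subtraction (-0.030), the authors' value table (0.016), within slide 2 (0.067), with the replicate block (0.059) and with trended robust eBayes, an estimated correlation or fry (0.10 in each), and reversed with array weights (-0.046) and without PB-NICD 1, with -0.067 to 0.19 when 1 array was left out. The androgen list lost its call with no background subtraction (-0.076), the sample channel alone (-0.14), signal on all 7 arrays (-0.28), the authors' value table (-0.20), within slide 2 (-0.10), with array weights (-0.19) and with trended robust eBayes, an estimated correlation or fry (-0.35 in each), with -0.48 to -0.23 when 1 array was left out. The basal list lost its call with no background subtraction (-0.25), signal on all 7 arrays (-0.16), the authors' value table (-0.24), slide as a fixed block (-0.19), within slide 1 (-0.28), with the replicate block (-0.16), array weights (-0.19) and an estimated correlation (-0.16), with -0.33 to -0.14 when 1 array was left out. The fibroblast list lost its call with no background subtraction (-0.17), processed signals (-0.15), median centring (0.056), the sample channel alone (-0.062), signal on all 7 arrays (-0.24), the authors' value table (-0.13), slide as a fixed block (-0.19), the replicate block (-0.23) and an estimated correlation or fry (-0.24 in each), and its test turned upward within slide 1 (-0.25), with -0.34 to -0.13 when 1 array was left out. An estimated correlation also ended the calls of smooth muscle (-0.55) and oxidative phosphorylation (-0.50), and fry that of oxidative phosphorylation (-0.50). Medians given with fry are over all tested members, but fry used those with values on all arrays, 25 of 36 in oxidative phosphorylation (-0.48), and 22 lists. On the same members camera kept the calls of the oxidative phosphorylation (adjusted p = 2.95e-07), androgen and fibroblast lists (adjusted p = 0.0429 each) but not of the cell cycle list (adjusted p = 0.0527). With 1 array left out the smooth muscle and oxidative phosphorylation lists kept their calls (-0.57 to -0.49 and -0.58 to -0.35). Median sample signals, as low as 69 over a background of 53 on control 1, limit what dim genes can show.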

Other observations

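The gene families and single genes of the first paragraphs, the splits that keep the slides, the comparison of the endoplasmic reticulum list with luminal genes, the general luminal genes in the array labelled PB-NICD 1 and the checks with each control set aside were chosen after the data were seen, and the other tests before their results were seen. Beside the folding genes of the fixed list, single genes of protein entry into the endoplasmic reticulum and of transport out of it fell. Of 21 measured genes of signal recognition, translocation and signal peptidase 12 fell and none rose (median -0.92), among them the translocon-associated Ssr4 (-1.85), the signal recognition particle gene Srp14 (-1.61) and the signal peptidase genes Spcs3 (-1.55) and Spcs1 (-1.47). Sec61b and Ssr1 also belong to the fixed list. Of 10 genes of the oligosaccharyltransferase, which attaches sugar chains to new proteins, 6 fell, among them Ostc (-1.27), Ost4 (-1.20) and Krtcap2 (-1.18), and the median was -0.90. Of 47 genes of cargo transport between endoplasmic reticulum and Golgi 13 fell, Mcfd2 (-1.98) and Tmed3 (-1.69) among them. Of 19 cytosolic aminoacyl-tRNA synthetase genes 4 fell, Sars (-1.13), Aars (-0.95), Nars (-0.94) and Lars. With an estimated correlation the unadjusted p of these families was 0.0370, 0.0361, 0.0944 and 0.0429 in the order given. Adjusted over the 8 families tested here and below, none passed, with 0.0858 the lowest. None of these 4 medians changed sign under another scaling.

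Among other families 5 of 77 cytosolic ribosomal protein genes fell (median -0.35, unadjusted p = 0.187 with an estimated correlation), with a positive median under median centring and in the sample channel alone. Relative to the median of all items, their median was -0.075 under median centring and 0.091 in the sample channel alone. Of 72 mitochondrial ribosomal protein genes 3 fell (median -0.27, unadjusted p = 0.295 with an estimated correlation), with a positive median under median centring. Relative to the median of all items it was -0.136 there. Metallothioneins, which bind metal ions, had 4 measured genes, too few for a test, of which Mt1 (-3.07), Mt2 (-3.18) and Mt3 (-1.45) fell. Mt1 and Mt2 are close in sequence, as are class I histocompatibility genes, and the array may not separate them, although no other scaling turned the direction of either family. Of 14 class I histocompatibility genes, which present peptides to T cells, H2-Q1 (1.66), H2-Q10 (0.87) and H2-Bl (0.78) rose and none fell (median 0.28, unadjusted p = 0.0282 with an estimated correlation). Of 8 tissue kallikreins Klk1b21 rose (median 0.29, unadjusted p = 0.133 with an estimated correlation). Further rises were those of the cyclin Ccnd2 (2.08), the water channel Aqp5 (1.77), the replication inhibitor Gmnn (1.61), the Wnt receptor Fzd6 (1.05), the ligand Wnt4 (0.99) and the chemokine Cxcl12 (0.90). Further falls were those of the protease Mmp7 (-2.79), the peroxidase Prdx6 (-2.67), the transcription factor Gata2 (-2.29) and the polyamine enzyme Odc1 (-1.66).

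The real grouping was set against all 35 ways to split the 7 arrays into 4 and 3. For the count of changed items 1 of 35 splits, the real one, gave as many as 461, a share below the threshold of 5%. The highest other gave 25, the split by slide. These splits do not keep the slides, although arrays of the same slide were alike, so this share alone does not exclude chance. Among the 18 splits that keep 1 of the 3 arrays on slide 1, fitted with slide as a fixed block, the real one gave 1232 and the highest other 11, and 18 splits are too few for a share under 5%. For the count of called lists chance cannot be excluded, since 9 of 35 splits gave 7 or more, and the highest other gave 8, in 3 splits, that by slide among them. With slide as a fixed block 5 lists were called, where 12 of the 18 splits gave 5 or more, and the fall of the endoplasmic reticulum list had a median of -1.42.

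The endoplasmic reticulum list fell with a median of -1.39, at percentile 0.010 (the smallest that so many draws can give) of 10000 random lists matched on brightness and mean ratio, whose medians centred on -0.32 and reached -0.96. This argues against an error of normalization that depends on intensity as the whole cause, while a share of about the matched lists' median stays open. In the reference channel the list differed by 0.106 (log2, PB-NICD minus control), the direction that would lower the ratio but too little to account for the fall. A lower share of luminal cells as the whole cause is argued against by the luminal list, below which the endoplasmic reticulum list lay by 0.950, 1.65 and 1.34 on the 3 PB-NICD arrays. An effect of the Notch1 domain, which the design names, and a loss of 1 secretory cell type or lobe stay open and untested.

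The array labelled PB-NICD 1 stood apart from the other PB-NICD arrays and read at the control level for Notch1 (0.64), Klk1b21 (0.50) and the second Heyl probe (0.24), all with outlier spots kept, and Nrarp (0.31), against 1.21 to 3.42 on the others. It lay beyond all controls in the direction of the other two for 59.5% of 974 genes called from them and in the opposite direction for 21.7%, whereas a control set aside lay beyond the other 3 controls for 26.9% to 46.6%, where PB-NICD 1 did so for 58.3% to 66.4%. This, and the endoplasmic reticulum list at -1.62 where each control lay at -0.17 to 0.14 against the other 3, argue against a control prostate under a PB-NICD label, although the share foreseen for a control, that of chance, was too low, and whether this sample expressed the Notch1 domain stays open. With the slide difference of the controls taken out its mean correlation with the others rose from 0.834 to 0.879, short of the 0.954 between them, which argues against slide as the whole cause. A lower share of luminal cells may contribute and cannot be told apart, since the general luminal genes had a median of -0.507 on this array but ran from -1.81 for Cdh1 to 0.81 for Krt19, and the rule that all 5 had to be lower was set after their values were seen.

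On control 2 the seminal vesicle genes Svs4 and Svs5 read 9.36 and 8.33, against -0.28 to 2.35 for Svs4 and -0.21 to 3.73 for Svs5 on the other controls. The array labelled PB-NICD 1 read 3.42 for Svs4 and, with outlier spots kept, 5.70 for Svs5, so all 3 arrays of slide 1 lay above those of slide 2. Seminal vesicle tissue in the sample of control 2 is a candidate source, and of the list's 5 other probes 60% were highest on control 2, Pate4 at 4.56, Svs6 at 4.41 and, with outlier spots kept, Svs2 at 3.20, while Aoc1 (-0.22) and Sva (-0.09) lay near 0. The probes that stayed low and the other arrays of slide 1 keep this open. Beyond carried-over tissue no explanation, slide and biological ones included, was tested, and without control 2 the fit gave 232 changed items.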
